A study of Mus musculus with 13 samples.

How the data were processed

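Per the labels, microglia were isolated from whole mouse brain without perfusion. The meninges were removed, the tissue was digested with papain at 37 °C, debris was removed, and cells were selected with magnetic beads against CD11b. RNA was made into libraries with a modified Smart-Seq2 protocol, which primes on poly(A) tails, followed by a tagmentation kit that does not mark the strand. The titles give postnatal day 4 and the series text a span of postnatal days 3 to 5. The labels name RSEM, STAR and DESeq2 without versions or roles. The genome build, the annotation release, the agent given to the dams, the sex, the litter and the sequencing batch are not given in the sources used here, so no coordinates are printed.

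The authors deposited 1 table of expected counts per gene, estimated counts that need not be whole numbers, with no normalization across libraries. It holds 55487 genes and 13 libraries, each column mapped to its sample by group and replicate number. Gene symbols were assigned by Ensembl gene ID: 54349 IDs matched exactly and 55141 with or without the version. Of the nonzero values 20.6% were not whole; all were rounded, which moved a value by at most 0.5. Totals ran from 25387100 to 35593500 counts per library. The gene CT010467.1 took 14.6 to 18.8% of the counts. A count of 3, the limit that a count of 0 allows, was 0.0843 to 0.118 CPM. Reads carried no molecular identifiers, so this limit and the counting interval of Fam19a4 cover counting error only.

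Samples were grouped as the titles give them: 5 retained CON, 5 retained MIA, and 3 libraries whose titles mark them as excluded, which entered only named alternatives and values without a test. The reason for their exclusion is not given in the sources used here. Genes were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM scaling, robust quasi-likelihood fit, group as the only term) and a Benjamini-Hochberg threshold of 0.05 over 15511 genes. CPM values are scaled by TMM. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic. Log2 CPM values of libraries use a prior count of 2, and the list value of a library is the mean over the measured members. Lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 27 lists with at least 3 measured members. Camera was repeated with an estimated correlation, and fry was run beside it. Mean log2 fold changes of lists come from the voom fit, which weights observations. Comparisons of single values between groups used 2-sided exact permutation tests, whose smallest possible p is 0.00794 for 5 against 5 libraries.

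The gene lists, the alternatives and the rule for named genes were set before the data were examined, except where stated. The rule took genes past the edgeR threshold with a symbol that is not a clone or predicted-model name and with at least 4 of the 5 MIA libraries on the side of the control median given by the fold change. Of these, the 10 rising and the 10 falling genes with the largest log2 fold change were taken, with list members that passed. Up to 4 of the most abundant members of each list were named whether or not they passed. Some genes that the rule takes are not given here. The lists were microglia homeostatic, early postnatal and disease-associated microglia, inflammatory cytokines and NF-kB, interferon response, antigen presentation, complement and phagocytosis, cell cycle, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrial genome transcripts, glycolysis, cholesterol synthesis, glucocorticoid response, tissue dissociation and immediate early genes, and markers of border-associated macrophages, monocytes, neutrophils, lymphocytes, erythroid cells, neurons, neural progenitors, astrocytes, the oligodendrocyte lineage, endothelium, mural cells and fibroblasts, choroid plexus and ependyma, and sex. Mertk, Dusp1 and Cd163 each stand in more than 1 list, and Sparc, Fn1, Csf3r and Slc2a1 are also expressed outside the cell type or process of their list.

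The pipeline was tested on simulated data with 5 against 5 libraries and 15190 genes. It recovered 31.3% of genes simulated with a 1.5-fold change, 50.8% with a 2-fold and 83.3% with a 4-fold change. Of its 121 calls 4.13% were false, and only the list that had been changed was called. Genes were drawn independently, whereas the estimated correlation in the data was 0.66 in the homeostatic and 0.75 in the endothelial list. The simulation therefore does not test list calls when genes of a list vary together. Alternatives were a replicate block, all 13 libraries, other scalings, no filter and a strict filter of 10 CPM in 5 libraries. Covariates were the neuronal and dissociation list means and a sex-linked value, the mean of Y-linked genes minus Xist in log2 CPM. Further alternatives were a surrogate variable (sva 3.50.0), DESeq2 1.42.0, limma-voom with and without quality weights, a threshold of 0.1, and leaving out each retained library in turn. Chosen after seeing the data were fits without CON 1 and CON 2, an endothelial covariate, both together, all 13 libraries without CON 1 and CON 2, and the exact permutation test of list means. The 7 contrasts between pairs of lists, and the gene families below the report, tested with Fisher's exact test, were also chosen then.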

Results

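RNA was sequenced from microglia, the resident macrophages of the brain, pulled out of whole mouse brain on postnatal day 4 with magnetic beads against the surface protein CD11b. Pups of dams that went through maternal immune activation (MIA) were set beside control pups (CON); the agent given to the dams is not given in the sources used here. There were 5 retained libraries per group, and another 3 libraries, CON 6, MIA 6 and MIA 7, carry titles that mark them as excluded. Total counts ran from 25387100 to 35593500 over the 13 libraries. The retained control libraries held 31836800 ± 3307870 counts (SD, n = 5) and the retained MIA libraries 27563300 ± 1962080 (SD, n = 5; 2-sided exact permutation p = 0.0476). Between 19577 and 20956 genes had at least 1 count in a library. Xist, the RNA of the inactive X chromosome, had 0 counts in all 13 libraries, while Ddx3y of the Y chromosome had 1337 to 2191.

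The series asks how immune activation of the mother alters the microglia of her newborn pups. In the MIA libraries, genes of blood vessel endothelium were higher together and genes of microglial identity, complement and phagocytosis were lower together. The tight-junction gene Cldn5 went from 585 ± 139 to 1688 ± 414 CPM, read counts scaled to a common library size (SD, n = 5 each), a 2.89-fold rise. The microglial growth factor receptor Csf1r went from 6928 ± 780 to 4730 ± 466 CPM, and the lipid carrier Apoe from 11503 ± 1783 to 6714 ± 397 CPM. Genes of cholesterol synthesis and of neurons were higher in the MIA libraries as well. Of 15511 genes tested with edgeR, 1602 changed, 892 of them higher and 710 lower in MIA, at a Benjamini-Hochberg threshold of 0.05. Of the higher genes 440 were at least 2-fold higher, and of the lower genes 10 were at least 2-fold lower. Of 27 gene lists fixed in advance, 15 passed camera with its preset correlation, 9 of them higher and 6 lower in MIA. None passed with an estimated correlation, and 5 passed an exact permutation test of the library means. Other splits of the 10 retained libraries gave a median of 11 lists past camera with the preset correlation. A camera call below is therefore weak evidence on its own. Scaling to total counts alone gave 1036 higher and 496 lower genes. The count depended on which libraries entered: it was 659 with all 13 libraries, 636 of them shared with the 1602 genes, and 90 with all 13 libraries except CON 1 and CON 2, 67 of them shared. It was 1057 without MIA 4 and 1037 without MIA 5. With all 13 libraries 424 genes were higher and 235 lower, and with all 13 except CON 1 and CON 2 53 were higher and 37 lower. In fits without 1 retained library the lower genes varied more. They numbered 464 without CON 2, 382 without MIA 4 and 365 without MIA 5, while the higher genes stayed within 1.5 times in every such fit (672 to 1238). No gene passed edgeR with the endothelial or the neuronal list mean as a covariate (1708 and 1180 genes at an unadjusted p under 0.05). The group accounts for 89.1% and 88.7% of the variance of these covariates, so these fits leave little of the group difference to test.

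**Figure D1:**
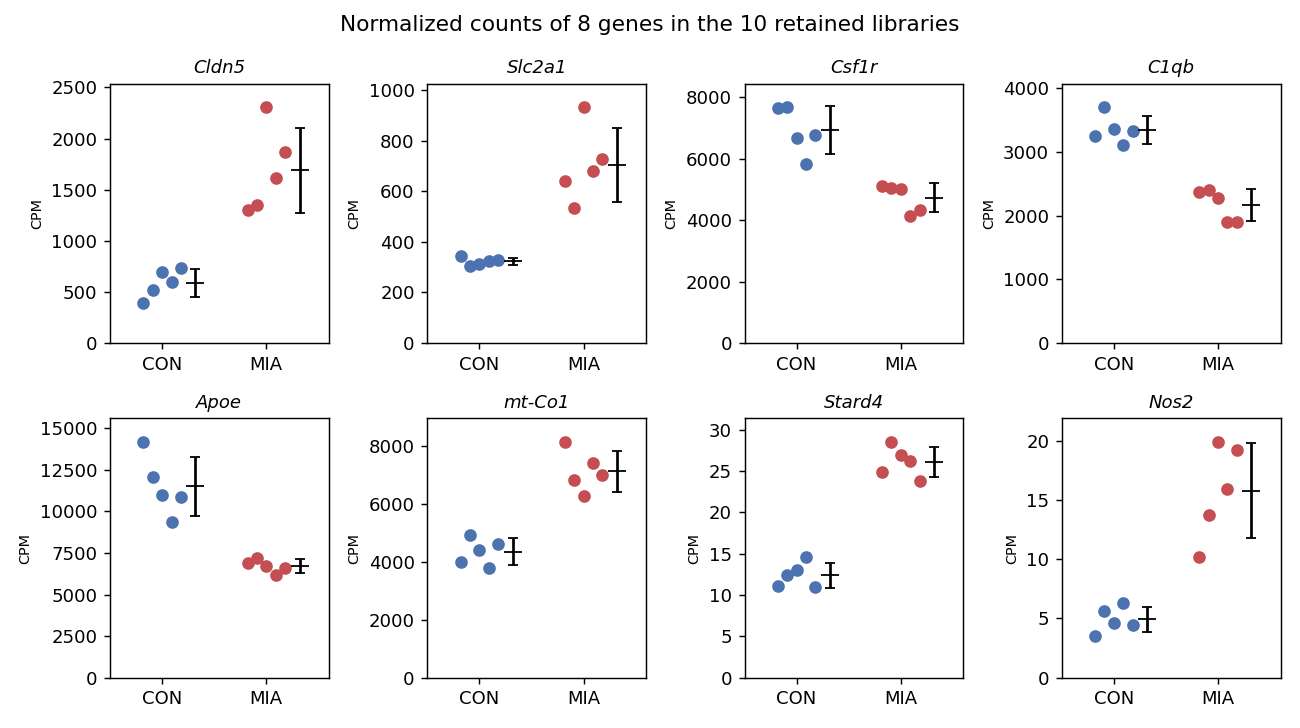
CPM (vertical axes, from 0) of 8 genes in the 5 retained CON and 5 retained MIA libraries; each point is a library, and the bar beside each group is its mean with SD. Cldn5, Slc2a1, mt-Co1, Stard4 and Nos2 lie higher in every MIA library than in every CON library, and Csf1r, C1qb and Apoe lie lower.

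All 10 measured endothelial genes rose in the MIA libraries. Their mean log2 CPM was 6.09 ± 0.25 in CON and 7.46 ± 0.28 in MIA (SD, n = 5 each), a 2.58-fold difference, with the 5 MIA libraries above the 5 control libraries. Cldn5 rose by 1.53 ± 0.20 on the log2 scale (SE; edgeR adjusted p = 0.000617). Kdr and Flt1, receptors for vascular endothelial growth factor, rose by 1.42 ± 0.17 and 1.40 ± 0.14 (SE). The endothelial adhesion genes Esam and Pecam1 rose by 1.46 ± 0.14 and 1.29 ± 0.14, and the angiopoietin receptor Tek by 1.46 ± 0.20 (SE). The smallest rise was that of Egfl7, 0.96 ± 0.14. 10 genes were higher as well when adjusted over the list alone. These genes as a list passed camera (adjusted p = 3.72e-15; adjusted p = 0.132 with an estimated correlation) and the exact permutation test of library means (adjusted p = 0.0429). With all 13 libraries, 9 of the 10 genes kept their call, and Cldn5 was at 1.06 with an edgeR adjusted p of 0.0525.

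Of 10 measured genes of the vessel wall and its fibroblasts, 3 rose: Dcn, a matrix proteoglycan, by 0.59 ± 0.13, Col1a1 by 0.53 ± 0.11 and Col1a2 by 0.45 ± 0.09 on the log2 scale (SE), both chains of type I collagen. The more abundant pericyte gene Rgs5 was at 284 ± 96.9 CPM in CON and 398 ± 77.7 in MIA (SD, n = 5 each), which did not pass. Col3a1, a fibrillar collagen, was at 134 ± 18.7 against 173 ± 23.2 CPM (edgeR adjusted p = 0.0502, and 0.0368 without CON 5), and Vtn, of vessel-wall cells, at 125 ± 21.7 against 156 ± 27.1 CPM. With values adjusted over the list alone, 4 genes were higher. Camera gave the list an adjusted p of 0.000144 (adjusted p = 0.290 with an estimated correlation), and the exact permutation adjusted p was 0.107. The endothelial shift exceeded the mural and fibroblast shift by 0.94 on the log2 scale (exact permutation p = 0.00794, the smallest that 5 against 5 libraries allow; adjusted p = 0.0556 over 7 such contrasts of lists).

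Neuronal transcripts were scarce in every library and higher in MIA, at a mean log2 CPM of 1.22 ± 0.20 in CON and 2.26 ± 0.21 in MIA (SD, n = 5 each). Of 14 measured neuronal genes, 6 rose and none fell. The neuronal tubulin gene Tubb3 went from 19.0 ± 4.18 to 43.1 ± 8.49 CPM, Stmn2 from 14.8 ± 1.88 to 28.8 ± 2.82 CPM, and the synaptic vesicle fusion gene Snap25 from 1.67 ± 0.495 to 5.08 ± 0.811 CPM. Map2, of the dendritic skeleton, was at 15.7 ± 6.50 and 20.8 ± 6.17 CPM and did not pass, except without CON 1 (edgeR adjusted p = 0.0293). Dcx, a gene of migrating young neurons, passed with a log2 fold change of 0.98 ± 0.28 (SE; edgeR adjusted p = 0.0451), and lost the call with all 13 libraries and in 7 of the 10 fits that left out 1 library (adjusted p up to 0.121, without MIA 2). Adjusted over the list alone, 8 neuronal genes were higher. As a list these genes passed camera (adjusted p = 2.30e-06; adjusted p = 0.0670 with an estimated correlation) and the exact permutation test (adjusted p = 0.0429). Among 8 neural progenitor genes, Sox11 and Dlx2 rose, by 1.37 ± 0.20 and 1.24 ± 0.35 (SE), with 4 higher adjusted over the list alone, while Nes was at 51.4 ± 10.2 and 66.6 ± 9.54 CPM. That list had a camera adjusted p of 0.00909 (adjusted p = 0.290 with an estimated correlation) and an exact permutation adjusted p of 0.122, and Dlx2 lost its call in 7 of the 10 fits without 1 library (edgeR adjusted p up to 0.117, without MIA 2).

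None of 12 astrocyte genes passed; Gja1 was at 148 ± 55.0 CPM in CON and 236 ± 66.1 in MIA, and Slc1a3 at 137 ± 83.6 and 153 ± 40.9 CPM; without CON 1, Gja1, a gap junction gene, had an edgeR adjusted p of 0.0441. None passed when adjusted over the list alone. The astrocyte list did not pass camera (adjusted p = 0.138), but did so without CON 1 (adjusted p = 0.000685) and without MIA 3 (adjusted p = 0.0438). In the oligodendrocyte lineage 1 of 13 genes rose, the precursor receptor gene Pdgfra, from 13.3 ± 3.24 to 28.4 ± 5.64 CPM. Cnp, a myelin gene, was at 100 ± 20.1 and 79.1 ± 10.1 CPM without passing, and the list had a camera adjusted p of 0.205, or 0.0243 without MIA 1. None of the 6 choroid plexus and ependymal genes passed (camera adjusted p = 0.908), and Ttr, the transthyretin gene of the choroid plexus, varied widely, at 5429 ± 6359 CPM in CON and 6491 ± 4862 in MIA.

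Genes that mark resting microglia were lower in the MIA libraries, in which the endothelial list was higher. Of 17 homeostatic genes, 14 fell and none rose, and the mean log2 CPM of the list was 9.72 ± 0.13 in CON and 9.24 ± 0.18 in MIA (SD, n = 5 each), a ratio of 0.720. Csf1r had a log2 fold change of −0.55 ± 0.10 (SE; edgeR adjusted p = 0.00282) and the fractalkine receptor gene Cx3cr1 −0.50 ± 0.10. Siglech was at −0.64 ± 0.08 and Tmem119 at −0.62 ± 0.12. The purinergic receptor gene P2ry12 fell by 0.50 ± 0.14 (SE; edgeR adjusted p = 0.0353), but did not pass without CON 2, CON 3, CON 5, MIA 3, MIA 4 or MIA 5, each left out alone (adjusted p up to 0.106). Sparc, which blood vessels also express, was at 1896 ± 162 and 2029 ± 130 CPM and did not pass. With values adjusted over the list alone, 16 genes were lower. The list passed camera (adjusted p = 3.43e-12; adjusted p = 0.271 with an estimated correlation) and the exact permutation test (adjusted p = 0.0429). With the endothelial covariate its mean log2 fold change went from −0.47 to −0.12 and the camera call was lost (adjusted p = 0.280). With that covariate and without CON 1 and CON 2 it was −0.054 (camera adjusted p = 0.459). Over the 10 retained libraries the group accounts for 89.1% of the variance of that covariate. Such fits therefore cannot show whether endothelial RNA accounts for the fall. With all 13 libraries, 2 of the 14 genes kept their call.

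Complement and phagocytosis genes shifted by a like amount. Of 20 measured, 16 fell and none rose. The 3 chains of the complement starter C1q, encoded by C1qa, C1qb and C1qc, fell by 0.62 ± 0.10, 0.63 ± 0.09 and 0.57 ± 0.09 on the log2 scale (SE). C1qb went from 3347 ± 221 to 2168 ± 249 CPM (SD, n = 5 each). The lipid-sensing receptor gene Trem2 fell by 0.60 ± 0.11, its signalling partner Tyrobp by 0.54 ± 0.11 and the lysosomal membrane gene Lamp1 by 0.45 ± 0.07. Itgam, which encodes the CD11b used for the bead sort, fell by 0.60 ± 0.08 (SE), from 500 ± 34.9 to 331 ± 30.6 CPM. Adjusted over the list alone, 16 were lower too. This list passed camera (adjusted p = 4.47e-15; adjusted p = 0.137 with an estimated correlation) and the exact permutation test (adjusted p = 0.0429). The mean log2 fold change, −0.47, was −0.41 with the endothelial covariate (camera adjusted p = 9.05e-05). It was −0.11 without a call when CON 1 and CON 2 were left out too (camera adjusted p = 0.0523). As the group accounts for 89.1% of the variance of that covariate, these fits leave little of the group difference to test. With all 13 libraries, 6 of the 16 genes kept their call.

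Among 20 genes of early postnatal and disease-associated microglia, 4 fell and none rose in the MIA libraries, in which endothelial genes were higher. These were Apoe, by 0.78 ± 0.10 on the log2 scale (SE; edgeR adjusted p = 0.000481), the protease gene Ctsb by 0.54 ± 0.12, the endosomal gene Cd63 by 0.48 ± 0.08 and the protease inhibitor Cst7 by 0.72 ± 0.20. Spp1, or osteopontin, was at 3107 ± 1798 CPM in CON and 2350 ± 807 in MIA, and Ctsl at 2730 ± 644 and 1953 ± 262 CPM; neither passed, although Ctsl did without CON 1 (edgeR adjusted p = 0.00131). Cst7 lost its call in 7 of the 10 fits without 1 library (edgeR adjusted p up to 0.112, without MIA 5). 1 gene was higher and 8 were lower when adjusted over the list alone. As a list these genes passed camera (adjusted p = 0.000199; adjusted p = 0.490 with an estimated correlation) and not the exact permutation test (adjusted p = 0.466); their mean log2 fold change, −0.27, was −0.46 without CON 1 and −0.15 without CON 5. Of 14 antigen presentation genes, 6 fell, among them Tapbp by 0.32 ± 0.08 and Tap1 by 0.35 ± 0.10, of the peptide-loading complex, and the immunoproteasome gene Psmb8 by 0.45 ± 0.11. The class I genes B2m, at 1313 ± 264 and 1049 ± 196 CPM, H2-D1, at 516 ± 76.9 and 444 ± 19.8, and H2-K1, at 231 ± 58.3 and 191 ± 5.07, did not pass, except H2-D1 and H2-K1 without CON 1 (edgeR adjusted p of 0.0259 and 0.0173). Tap1 lost its call in 8 of the 10 fits without 1 library, Tapbp without CON 2, CON 5, MIA 4 or MIA 5, and Psmb8 without MIA 5 (edgeR adjusted p up to 0.120, 0.0781 and 0.0508). With values adjusted over the list alone, 6 were lower. Camera gave that list an adjusted p of 0.000199 (adjusted p = 0.290 with an estimated correlation), and the exact permutation adjusted p was 0.273. Its mean log2 fold change, −0.28, was −0.46 with the endothelial covariate (camera adjusted p = 0.00317). It was 0.18 with that covariate and without CON 1 and CON 2 (camera adjusted p = 0.453). That covariate shares 89.1% of its variance with the group, so these values carry little information.

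Cytokine genes differed widely among the control libraries, and few separated the groups. Of 25 inflammatory and NF-kB genes, Nos2, the inducible nitric oxide synthase, rose from 4.92 ± 1.09 to 15.8 ± 4.02 CPM and Tlr4, the lipopolysaccharide receptor, fell from 101 ± 21.0 to 64.4 ± 10.6 CPM (SD, n = 5 each). The chemokine genes Ccl4, at 666 ± 511 and 862 ± 184 CPM, and Ccl3, at 563 ± 376 and 762 ± 181, did not pass, nor did Cd83, at 1100 ± 731 and 1365 ± 207, or the inhibitor Nfkbia, at 587 ± 448 and 684 ± 93.8. Adjusted over the list alone, 1 gene was higher and 1 lower. Mean log2 CPM of the list was 4.88 in CON 1 and 5.36 in CON 2, and between 7.30 and 7.49 in the other 3 retained controls, against 7.15 ± 0.10 in MIA. Camera put the list higher in MIA (adjusted p = 0.0300; adjusted p = 0.696 with an estimated correlation) and, without CON 1 and CON 2, lower (mean log2 fold change −0.22, adjusted p = 0.000218). The exact permutation adjusted p over all 10 libraries was 0.536. The call was also lost without CON 1, CON 2, MIA 1 or MIA 2 alone, with adjusted p of 0.410, 0.289, 0.0674 and 0.0584. None of 22 interferon response genes passed (camera adjusted p = 0.105). Bst2 was at 68.8 ± 11.7 and 53.9 ± 4.94 CPM (edgeR adjusted p = 0.00581 without CON 1), Trim30a at 57.9 ± 9.76 and 49.7 ± 9.09, and Cxcl10 at 152 ± 131 and 206 ± 42.4; the list passed as lower without CON 1 (adjusted p = 0.0213) and without CON 4 (adjusted p = 0.0436).

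The same control libraries stood apart in genes induced by tissue dissociation. Mean log2 CPM of the 24 immediate early and heat-shock genes was 5.93 in CON 1 and 5.97 in CON 2, and lay between 7.45 and 7.87 in the other 11 libraries. Klf4, a transcription factor, rose from 8.46 ± 4.04 to 19.4 ± 1.27 CPM (SD, n = 5 each) and no other member passed, adjusted over the list alone included; Klf4 lost its call without MIA 3, MIA 4 or MIA 5 (edgeR adjusted p up to 0.0592). Hspa8 was at 3012 ± 645 and 2828 ± 86.5 CPM, Fos at 1368 ± 719 and 1420 ± 98.0, Egr1 at 1238 ± 760 and 1114 ± 82.4, while Nr4a1 had a log2 fold change of 0.51 ± 0.66 (SE). Camera put the list higher in MIA (adjusted p = 0.0416; adjusted p = 0.696 with an estimated correlation), and lower without CON 1 and CON 2 (mean log2 fold change −0.24, adjusted p = 1.03e-06), while the exact permutation adjusted p over all 10 libraries was 0.536. The list did not pass without CON 1 (adjusted p = 0.526), CON 2 (0.509), MIA 1 (0.0755), MIA 2 (0.0584) or MIA 3 (0.0732), each left out alone. Red blood cell transcripts followed these libraries too: the erythroid list had a mean log2 CPM of 0.80 in CON 1, 1.22 in CON 2 and 4.97 to 6.46 in the other 11 libraries. The haemoglobin genes Hbb-bs, at 417 ± 383 and 844 ± 193 CPM, and Hba-a1, at 238 ± 214 and 514 ± 148, have near-identical copies that share reads, and none of the 7 erythroid genes passed; the list had a camera adjusted p of 0.00229 (adjusted p = 0.509 with an estimated correlation) and an exact permutation adjusted p of 0.161.

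**Figure D2:**
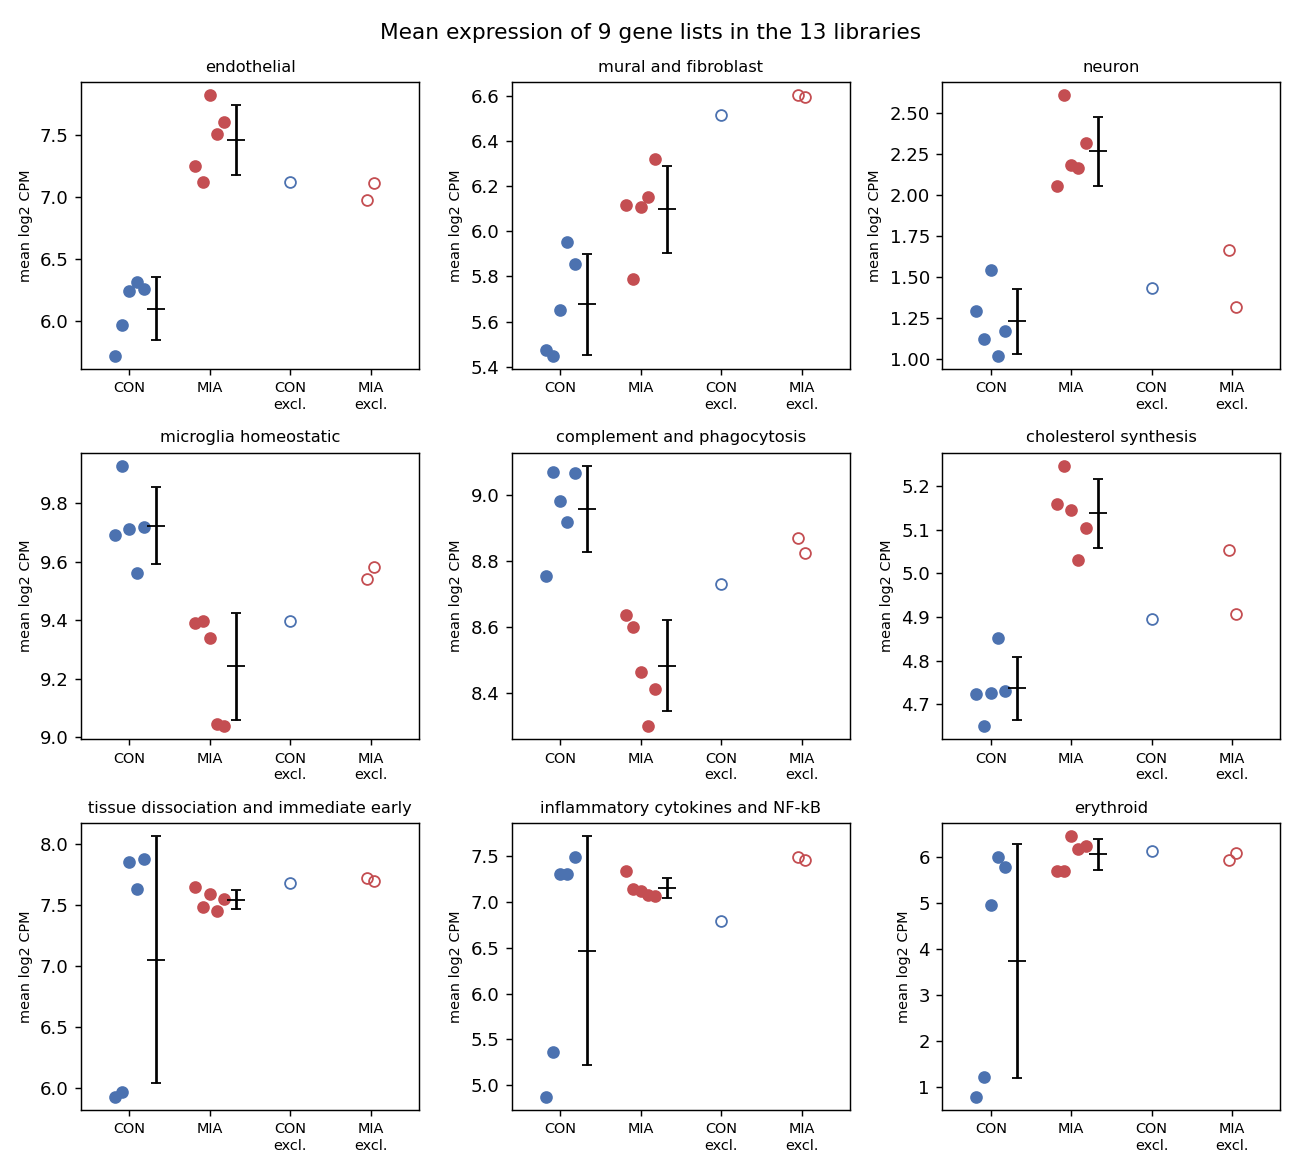
Mean log2 CPM (vertical axes) of 9 gene lists in the 13 libraries; filled points are the retained CON and MIA libraries with the group mean and SD beside them, open points the 3 excluded libraries. The endothelial, neuron and cholesterol lists are higher and the homeostatic and complement lists lower in every retained MIA library than in every retained CON library, and CON 1 and CON 2 lie far below all others in the bottom panels.

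Genes of cholesterol synthesis and uptake were higher in MIA, at a mean log2 CPM of 4.73 ± 0.07 in CON and 5.14 ± 0.08 in MIA (SD, n = 5 each). Of 19 measured, 6 rose and none fell. Stard4, a carrier of cholesterol between membranes, rose 2.10-fold, by 1.07 ± 0.11 on the log2 scale (SE; edgeR adjusted p = 0.000127). The synthesis enzymes Idi1, Fdps and Cyp51 rose by 0.59 ± 0.13, 0.52 ± 0.10 and 0.41 ± 0.08. Hmgcs1, at 107 ± 10.9 and 134 ± 15.6 CPM, fell short of the threshold, with an edgeR adjusted p of 0.0527, and passed without CON 1 or MIA 3 (0.0235 and 0.0216). 10 genes were higher when adjusted over the list alone. The list passed camera (adjusted p = 2.75e-07; adjusted p = 0.0670 with an estimated correlation) and the exact permutation test (adjusted p = 0.0429). With all 13 libraries, 4 of the 6 genes kept their call. In the retained MIA libraries the endothelial and neuron lists were higher too, by 1.37 and 1.04 in mean log2 CPM.

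Transcripts of the mitochondrial genome took 2.69 ± 0.459% of counts in CON and 3.84 ± 0.399% in MIA (SD, n = 5 each; 2-sided exact permutation p = 0.00794). Of the 13 protein-coding ones, 5 rose and none fell, with mt-Co1, of cytochrome c oxidase, up by 0.71 ± 0.09, mt-Cytb by 0.59 ± 0.11 and mt-Co2 by 0.56 ± 0.10 on the log2 scale (SE). The abundant mt-Nd1 was at 2234 ± 767 and 2840 ± 394 CPM and did not pass, except without CON 2 (edgeR adjusted p = 0.0271). With values adjusted over the list alone, 6 were higher. Endothelial and neuron lists rose in the same MIA libraries, by 1.37 and 1.04 in mean log2 CPM. Camera called the list (adjusted p = 0.000248; adjusted p = 0.384 with an estimated correlation), and the exact permutation test of its library means did not (adjusted p = 0.321). Its mean log2 fold change was 0.21, against 0.12 without MIA 1, 0.31 without CON 2 and 0.026 with all 13 libraries, with which 2 of the 5 genes kept their call. None of the 79 nuclear genes of oxidative phosphorylation passed, with Atp5b at 1061 ± 62.2 and 1071 ± 26.9 CPM and Atp5a1 at 676 ± 31.6 and 669 ± 30.0 CPM (camera adjusted p = 0.0625, and 0.00546, 0.00860 and 0.0109 without CON 1, CON 3 or MIA 3). Of 17 glycolysis genes, 2 rose: Slc2a1, the glucose transporter of brain vessels among other cells, by 1.13 ± 0.12, and the phosphofructokinase gene Pfkp by 0.98 ± 0.17 (SE). Gapdh, at 1274 ± 166 and 1123 ± 7.84 CPM, and Pkm, at 1050 ± 178 and 1006 ± 88.2, did not pass. Adjusted over the list alone, 3 were higher and 1 lower. The mean log2 fold change of that list, 0.12, and its median, −0.04, differed in sign (camera adjusted p = 0.604).

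Of 85 cytosolic ribosomal protein genes, many of which have processed copies that can share reads, 4 fell, among them Rps25 by 0.34 ± 0.07 on the log2 scale (SE). Rplp0 was at 1536 ± 71.3 and 1482 ± 147 CPM and Rpl4 at 1138 ± 73.3 and 1107 ± 84.4. 1 gene was lower when adjusted over the list alone. The list, with a mean log2 fold change of −0.13, passed camera (adjusted p = 4.93e-09; adjusted p = 0.562 with an estimated correlation) but not the exact permutation test (adjusted p = 0.214), and none of the 4 genes kept its call with all 13 libraries. None of 20 cell cycle genes passed: Mcm6 was at 220 ± 39.8 and 207 ± 17.1 CPM, Mcm3 at 227 ± 39.2 and 199 ± 17.4, Top2a at 210 ± 52.6 and 211 ± 25.2 and Pcna at 197 ± 41.1 and 192 ± 14.6 (camera adjusted p = 0.521, and 0.000459, as lower in MIA, without CON 1). Among 10 glucocorticoid response genes, Tsc22d3 rose by 0.39 ± 0.08 and Klf9 by 1.04 ± 0.29 (SE), while Mertk, a receptor for engulfing dying cells, fell by 0.53 ± 0.09. Klf9 lost its call in 7 of the 10 fits without 1 library (edgeR adjusted p up to 0.101, without MIA 5). With values adjusted over the list alone, 3 were higher and 1 lower. Dusp1 was at 469 ± 250 and 542 ± 55.4 CPM, and the list did not pass camera (adjusted p = 0.480).

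**Figure D3:**
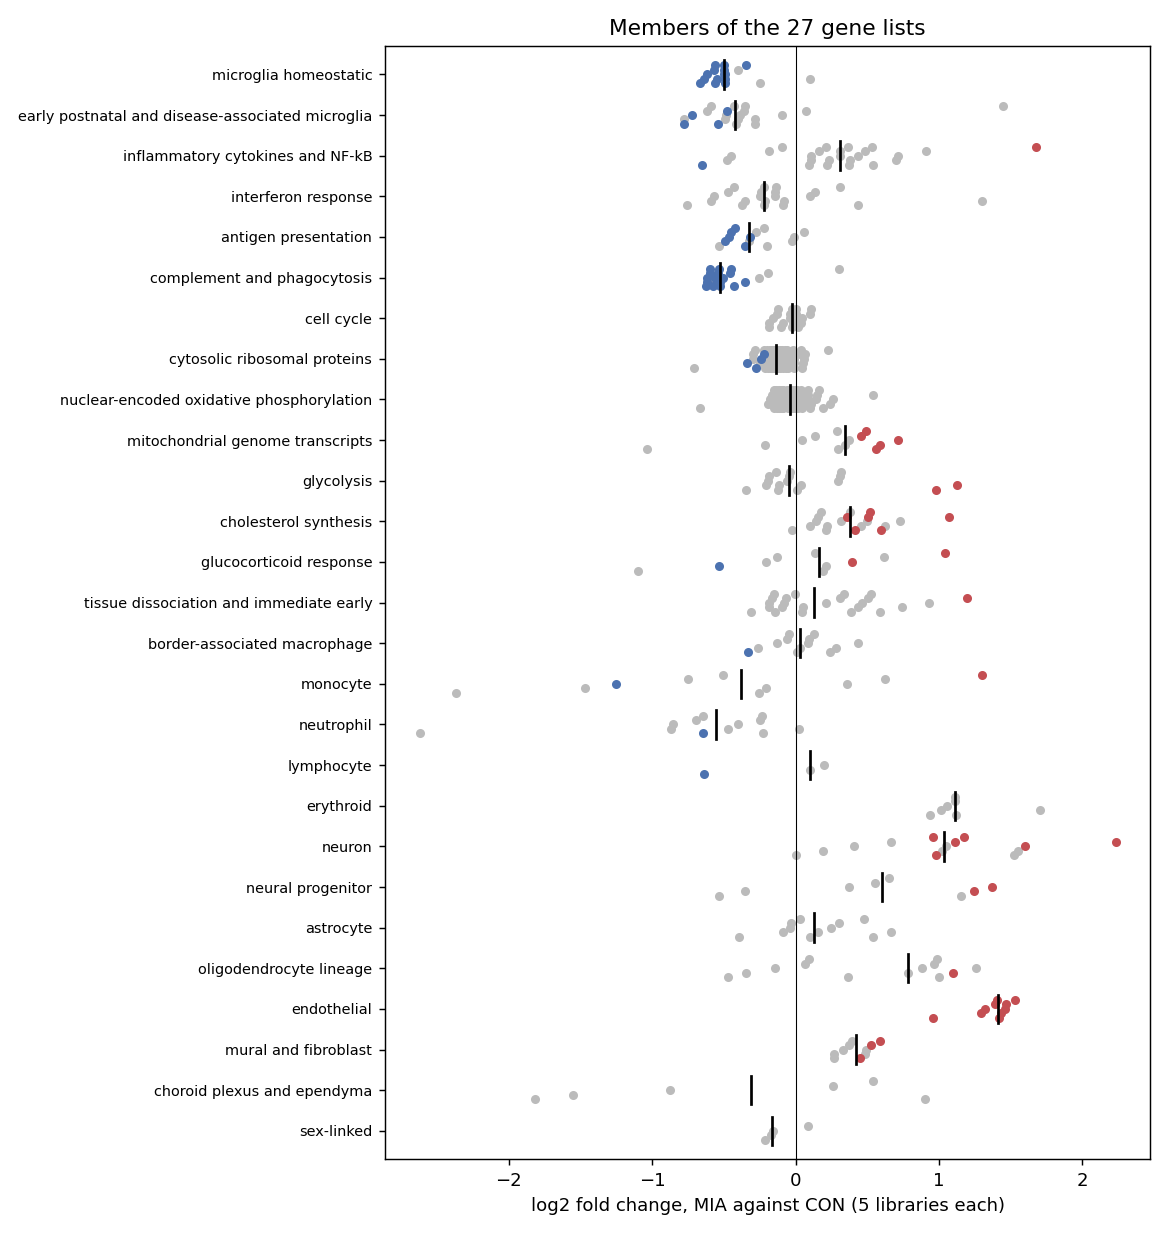
Log2 fold change of each measured member of the 27 gene lists (horizontal axis, MIA against CON, 5 libraries each); red points rose and blue points fell past an edgeR adjusted p of 0.05, grey points did not pass, and black ticks are list medians. All 10 endothelial points are red, and 14 of 17 homeostatic and 16 of 20 complement points are blue.

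Other blood and border cells showed few changes. Among 13 genes of border-associated macrophages, the scavenger receptor gene Stab1 fell by 0.34 ± 0.09 on the log2 scale (SE) and none rose; the call was lost in 7 of the 10 fits without 1 library (edgeR adjusted p up to 0.0758, without CON 5). Mrc1 was at 783 ± 117 and 750 ± 198 CPM and Dab2 at 558 ± 113 and 592 ± 138. That list had a mean log2 fold change of 0.03, with camera ranking it lower (adjusted p = 0.604). Of 10 monocyte genes, Fn1, the fibronectin gene, which vessels also express, rose from 147 ± 25.3 to 363 ± 74.7 CPM and Ms4a4c fell by 1.25 ± 0.29 on the log2 scale (SE), with Plac8 at 9.37 ± 6.70 and 6.60 ± 1.66 (camera adjusted p = 0.604). Of 12 neutrophil genes, Csf3r, which microglia also express, fell from 114 ± 18.8 to 73.0 ± 7.16 CPM, and S100a8, of the calprotectin complex, was at a log2 fold change of −0.87 ± 0.28 (SE; edgeR adjusted p = 0.0765, and 0.0399 and 0.0494 without CON 3 or CON 4). Adjusted over the list alone, 4 neutrophil genes and 2 monocyte genes were lower. The neutrophil list had a camera adjusted p of 0.00672 (adjusted p = 0.439 with an estimated correlation) and an exact permutation adjusted p of 0.236. Only 3 of 12 lymphocyte genes could be tested, of which Cd79b fell from 59.0 ± 7.16 to 37.9 ± 4.87 CPM. Cd79a was at 0.502 ± 0.266 and 0.582 ± 0.304 CPM and Ms4a1 at 0.271 ± 0.265 and 0.297 ± 0.246. With these so far below Cd79b, its fall cannot be assigned to lymphocytes. The mean log2 fold change of the lymphocyte list, −0.02, and its median, 0.21, differed in sign (camera adjusted p = 0.309). None of 4 measured sex-linked genes passed (camera adjusted p = 0.480), with Ddx3y at 56.4 ± 3.47 and 59.8 ± 8.39 CPM.

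The genes with the largest rises were all scarce. Fam19a4, which encodes a secreted chemokine-like protein, had 1 count in the 5 control libraries together and 113 in the 5 MIA libraries, a depth-corrected ratio of 131 (95% interval from counting error 23.0 to 5200). That count was in CON 3, while the excluded CON 6 alone had 5, MIA 6 had 11 and MIA 7 had 9, against 11 to 27 in the retained MIA libraries. The edgeR log2 fold change of 6.26 became 7.56 without CON 3, 4.17 with all 13 libraries and 3.66 (adjusted p = 0.0643) with all 13 without CON 1 and CON 2. Without CON 3 the controls had no count, so 7.56 depends on how the fit treats an empty group. Fam19a4 was followed by Syt16, at 0.349 ± 0.188 and 1.79 ± 0.543 CPM (log2 fold change 2.34 ± 0.46, SE), Epp13 (2.30 ± 0.53), Foxf1 (2.25 ± 0.46), Gfod1 (2.24 ± 0.47) and Mogat2 (2.24 ± 0.59). The remaining ones were the neuronal transcription factor Neurod6 (2.23 ± 0.50), the chemokine Ccl21a, which has near-identical copies (2.20 ± 0.65), the neuronal sodium channel Scn2a (2.09 ± 0.47) and Eda2r (2.06 ± 0.57). Among the falling genes, Xdh, or xanthine dehydrogenase, went from 5.75 ± 1.41 to 1.90 ± 0.680 CPM, a log2 fold change of −1.60 ± 0.30 (SE; edgeR adjusted p = 0.00398). Next came Tmem81 (−1.40 ± 0.39), Fxyd2 (−1.37 ± 0.36), Ms4a4c (−1.25 ± 0.29), Zfp658 (−1.11 ± 0.23) and Calhm6 (−1.04 ± 0.21). Car9, a carbonic anhydrase, was at −1.02 ± 0.28, Tmem52 at −1.01 ± 0.29, the apolipoprotein Apoc1 at −0.95 ± 0.17 and Zfp39 at −0.94 ± 0.25. In each of these 20 genes all 5 MIA libraries lay on the same side of the control median. With all 13 libraries, of the genes in this paragraph only Fam19a4, Syt16, Neurod6, Eda2r and Zfp658 kept an edgeR adjusted p under 0.05. Leaving out single libraries ended the calls of Mogat2, Ccl21a, Eda2r, Tmem81, Fxyd2, Car9, Tmem52 and Zfp39 in 4 to 8 of the 10 fits, with edgeR adjusted p up to 0.0849, 0.115, 0.0870, 0.0995, 0.0730, 0.0973, 0.115 and 0.0807.

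In endothelial, neuronal and vessel-wall genes the 3 excluded libraries lay in different places against the retained groups. CON 6, MIA 6 and MIA 7 held 27186300, 30486100 and 25387100 counts and 20105, 20277 and 20286 genes, and the total of MIA 7 was the lowest of the 13. Their median Spearman correlations with the retained libraries, across genes, were 0.977, 0.981 and 0.979, each above that of every retained library (0.954 to 0.977). Endothelial expression in the excluded control, at a mean log2 CPM of 7.12, lay just above the lowest retained MIA library, and that in MIA 6 (6.98) and MIA 7 (7.11) lay below all retained MIA libraries and above all retained controls. Neuronal expression in CON 6, MIA 6 and MIA 7, at 1.43, 1.67 and 1.32, lay below all retained MIA libraries, the lowest of which was at 2.05, and in CON 6 and MIA 7 within the range of the retained controls, 1.02 to 1.54. Mural and fibroblast expression, at 6.52, 6.60 and 6.59, lay above all 10 retained libraries. On a scale on which the retained controls average 0 and the retained MIA libraries 1, computed over the 1602 changed genes, CON 6 lay at 0.719, MIA 6 at 0.581 and MIA 7 at 0.599. Retained libraries placed without their own contribution lay between −0.13 and 0.29 for CON and between 0.70 and 1.08 for MIA. The excluded libraries were not tested against the retained ones.

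**Figure D4:**
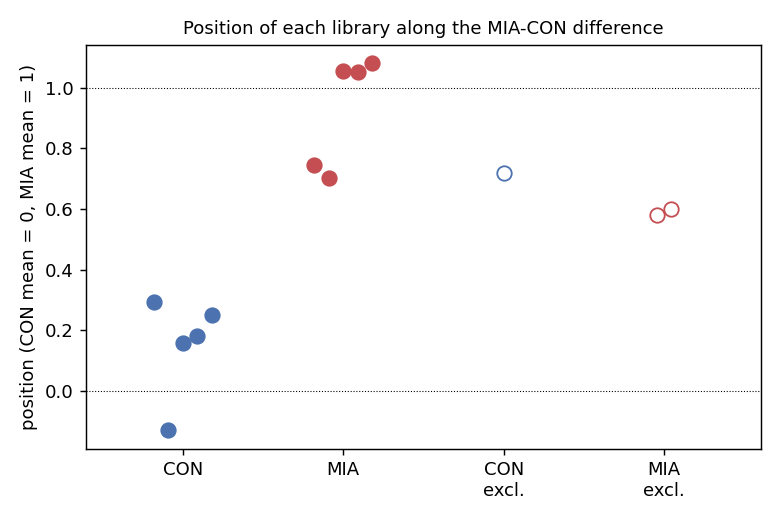
Position (vertical axis, CON mean 0, MIA mean 1) of each library along the difference between the retained groups; filled points are retained libraries, each placed with genes and means from the other 9, and open points are excluded libraries, placed with all 10. The excluded libraries lie from 0.581 to 0.719, above the retained controls, which reach 0.29, and near or below the lowest retained MIA library, at 0.70.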

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

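The tests of a common endothelial rise, of the endothelial against the mural or neuronal shift, and of microglial content in CON 1 and CON 2 were chosen only after the result was seen. So were the comparisons of library totals. The other tests in this part were planned.

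Endothelial genes were higher and microglial genes lower in the MIA libraries. Lower sequencing depth in MIA is argued against, since the endothelial shift was 1.36 on the log2 scale after all libraries were thinned to the smallest total. A lower share of microglia would raise every other cell type alike. The endothelial shift exceeded the mural and fibroblast shift by 0.94 (exact permutation p = 0.00794, adjusted p = 0.0556), which leans against it without passing after adjustment. The neuronal shift was not told apart from the endothelial one (difference −0.32, exact permutation p = 0.214). More endothelial cells passing the CD11b sort in the MIA preparations may account for the vascular part: all 10 members rose, led in abundance by Cldn5. The SD of their log2 fold changes, 0.16, was no larger than their mean SE, 0.17. That comparison cannot decide whether the rise was common to all members. The SE holds variation between libraries that the members share (estimated correlation 0.75), which does not spread their fold changes. Whether dilution by such RNA is the whole source of the microglial fall cannot be told apart from a change in microglia. The SD of the 37 homeostatic and complement members was 1.69 times their mean SE (0.20 against 0.12), between the bounds set for either answer. Those bounds took no account of shared variation either (estimated correlation 0.66 in the homeostatic and 0.45 in the complement list), so the ratio decides nothing. Sparc, which blood vessels also express and which did not fall, is among the 37 and widens their SD. The ratio without Sparc was not computed. An effect of maternal immune activation on vessels or microglia stays open and untested, as litter and batch are not given in the sources used here.

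CON 1 and CON 2 were lower than the other 11 libraries in immediate early, cytokine and haemoglobin genes. Shallower sequencing is argued against by a gap of 1.69 on the log2 scale in the dissociation list after thinning. Fewer microglia as the whole source are argued against, since the homeostatic list, at 9.69 in CON 1 and 9.93 in CON 2, averaged 0.14 above the other 3 retained controls (9.56 to 9.72); a smaller deficit is not excluded in CON 1, which had the lowest complement list of the retained controls, 8.76, and the highest astrocyte list (5.80) and choroid plexus list of the 13 libraries. Different handling before lysis stays open and undecided: that 29 of 31 dissociation and erythroid members, or 93.5%, lay below all other 11 libraries in both restates the pattern. No biological explanation was tested.

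On the changed genes MIA 6 and MIA 7 lay between the groups and CON 6, at 0.719, within the range of the retained MIA libraries. A swap of CON 6 with an excluded MIA library is argued against, since the lowest excluded MIA library lay at 0.581 and the retained controls reached only 0.29. A level of endothelial and microglial RNA between those of the groups may describe them on those lists, with the lowest of the 3 at 0.526, but not on the mural list, where all 3 lay above both groups. A single wrong label on CON 6 stays open. Its neuronal list, at 1.43, and its mitochondrial share, at 2.65%, lay within the range of the retained controls and below all retained MIA libraries. Both measures also lay below all retained MIA libraries in MIA 6 (1.67 and 2.20%) and in MIA 7 (1.32 and 3.02%). They therefore do not tell the groups apart among the excluded libraries and cannot decide about the label. No biological explanation was tested.

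Other splits of the 10 libraries asked whether grouping by chance gives as many calls. Of 100 splits, 1, the real one, gave as many as 1602 changed genes, and the highest other gave 26. This argues against chance for the gene count among these 10 libraries. The splits took the exclusion of 3 libraries as given, and the count was 659 with all 13. For lists, 19 of 100 gave at least the real 15, with the highest other at 19, so chance is not excluded for the number of lists. The other splits gave a median of 11 lists and of 0 genes. Camera with the preset correlation therefore called many lists for groupings other than the real one.

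Of 334 tests for a library far from the other 4 of its group, 27 were positive, and chance gives about 1 in 20. Among lists, in mean log2 CPM, the inflammatory list of MIA 1 stood at 7.33 and the neural progenitor list of MIA 2 at 3.12, above the other MIA libraries, and the border-associated macrophage list of MIA 3 at 5.97, below them. In CON 1 the cell cycle list stood at 6.09 and the ribosomal list at 7.72, below the other controls. Among genes of CON 1, Esam was at 78.1 CPM (104 to 112 in the other controls), Cst7 at 10.6, Rplp0 at 1413 and Slc38a5 at 81.0, below the others, and Map2 at 26.9, Fxyd2 at 4.13 and Tmem52 at 6.62 CPM, above them. In MIA 2, Tubb3 at 57.7 CPM (37.1 to 42.9 in the other MIA libraries), Map2 at 31.6, Sox11 at 55.6 and Dlx2 at 5.53 were above the others. Further controls were C1qa at 1546 CPM in CON 4, below the others, Tlr4 at 138 in CON 2, Atp5b at 1168 in CON 4 and Fam19a4 at 0.0291 in CON 3, above them. In MIA libraries, Col3a1 was at 214 CPM in MIA 5, Pcna at 217 in MIA 3, Dusp1 at 640 and Atp6ap1 at 358 in MIA 1, above the others, and Stab1 at 390 in MIA 3, Zfp658 at 5.77 in MIA 4 and Fam19a4 at 0.388 in MIA 5, below them.

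In the excluded libraries 10 of 81 list values lay outside the range of the 10 retained ones. Mural and fibroblast expression stood at a mean log2 CPM of 6.52 in CON 6, 6.60 in MIA 6 and 6.59 in MIA 7, and glycolysis at 7.88 in CON 6 and 7.87 in MIA 6, all above. In MIA 6 the glucocorticoid list at 5.30 and the border-associated macrophage list at 7.48 were above, and the mitochondrial genome list at 7.56 was below. In MIA 7 the lymphocyte list at 1.75 and the sex-linked list at 5.22 were above.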

How the results depend on the processing

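The fits without CON 1 and CON 2, those with an endothelial covariate, and the exact permutation test of list means were chosen only after the result was seen; the other alternatives were planned. The cause was not tested for any difference below unless stated.

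Of the gene count, 1602 with edgeR, 12 alternatives kept within 1.5 times. A replicate block gave 1524 (1361 shared). Whether replicate numbers pair the libraries is not known: same-number correlations, 0.0580 to 0.302, were all positive but low and cannot decide it. The count was 1606 with RLE, 1704 with upper-quartile scaling, 1479 unfiltered, 1426 with the strict filter and 1765 with the dissociation covariate. The count was 1774 with a surrogate variable, 2265 with DESeq2, 1675 with limma-voom and 2359 with quality weights. The count was 2273 at a threshold of 0.1 and 1966 without CON 1 and CON 2 (1338 shared). It was 659 with all 13 libraries, 90 with all 13 without CON 1 and CON 2, and 1039 with the sex-linked covariate (1010 shared). Xist had 0 counts and Y-linked genes were expressed in every library. That covariate therefore held variation of Y-linked genes between libraries, not a difference of sex, and cannot adjust for sex. It was 0 by edgeR with the neuron covariate (1180 at an unadjusted p under 0.05), 0 with the endothelial covariate (1708), and 0 with that covariate without CON 1 and CON 2 (984). The group accounts for 88.7% of the variance of the neuron covariate and 89.1% of that of the endothelial one, so these fits leave little of the group difference to test; no other tool was run with them. Leaving out single libraries gave 1037 (without MIA 5) to 2263 (without CON 1), within 1.5 times in all but the fits without MIA 4 or MIA 5. The 710 lower genes moved by more than that without CON 2 (464), MIA 4 (382) or MIA 5 (365), and the 892 higher genes in none of these fits.

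The 15 lists were 0 with an estimated correlation, 9 with fry, 5 with the exact permutation test, and 13 to 17 when single libraries were left out; other settings gave 13 to 20. List values outside the retained range in excluded libraries were 10, and 12 by total-count CPM.

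Lists whose direction by camera turned, with a call in at least 1 of the fits compared, had these mean log2 fold changes. A list whose own mean is the covariate is set near 0 in advance. The turns of the endothelial and dissociation lists with their own covariate therefore test nothing. Without CON 1 and CON 2, inflammatory was −0.22 and dissociation −0.24; with all 13 libraries without these, 0.018 (lower by camera) and −0.16. With the neuron covariate, oxidative phosphorylation was 0.22, neural progenitor −0.70 and oligodendrocyte −0.73. With the dissociation covariate, dissociation was 0.0091 (lower by camera). With the endothelial covariate, inflammatory was −1.86, glycolysis −0.36, dissociation −1.61, erythroid −2.88, endothelial 0.019 (lower by camera) and mural −0.35. With that covariate and without CON 1 and CON 2, dissociation was −0.23, border-associated macrophage 1.20, erythroid −0.72, endothelial 0.0070 (lower by camera) and mural −0.24. The mean alone changed sign in 2 called lists, which lost their call: early postnatal and disease-associated microglia, 0.13 with the neuron covariate, and antigen presentation, 0.18 with the endothelial covariate without CON 1 and CON 2. Other sign changes of a mean, such as glucocorticoid response at −0.16 with the neuron covariate, were in lists that passed in neither fit.

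Other calls ended without a turn, beyond those in fits without 1 library. With the endothelial covariate these were homeostatic (adjusted p = 0.280) and neutrophil (0.287), and with it and without CON 1 and CON 2 homeostatic (0.459), complement (0.0523), inflammatory (0.898) and neutrophil (0.293). With the neuron covariate they were inflammatory (0.458), dissociation (0.624), neutrophil (0.464) and neuron (0.665), and with the dissociation covariate inflammatory (0.542). The loss of the neuron list with its own mean as covariate was fixed in advance. Neutrophil lost its call with all 13 libraries (0.0560), neutrophil (0.0631) and erythroid (0.0903) with all 13 without CON 1 and CON 2, and dissociation with the replicate block (0.0624) and the strict filter (0.0779).

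Named genes turned direction in these fits, in log2 fold change. A list mean used as covariate sets the mean change of that list's own members near 0 in advance. Turns of endothelial list members with the endothelial covariate, and of Dcx with the neuron covariate, therefore test nothing. Without CON 1 and CON 2, Nfkbia was −0.43 and Fos −0.42. With the neuron covariate, Dlx2 was −0.13, Dcx −0.51, Pros1 0.076, Ccl21a −0.23 and Atp6ap2 0.024. With the endothelial covariate, Cldn5 was −0.18, Tek −0.31, Emcn −0.27, Kdr −0.093, Cdh5 −0.12, Klf4 −0.44, Egfl7 −0.061, Mvk −0.42, Foxf1 −0.16, Mogat2 −1.86, Col4a1 −0.65, Col4a2 −0.27, Ctsw −0.58 and Slc38a5 −0.27. In the same fit Tlr4 was 0.20, Fcgr3 0.024, P2ry12 0.022, Sall1 0.28, Cd33 0.20, Fxyd2 0.44, Tmem52 0.032, Zfp39 0.64 and Ctss 0.032. With that covariate and without CON 1 and CON 2, Cldn5 was −0.046, Tek −0.33, Kdr −0.18, Fn1 −0.10, Slc2a1 −0.067, Mvk −0.43, Mogat2 −2.02, Col4a1 −0.69, Col4a2 −0.75, Ctsw −0.15 and Slc38a5 −0.076. There Tlr4 was 0.32, Fcgr3 0.10, P2ry12 0.023, Sall1 0.16, Psmb8 0.045, Lamp2 0.10, Cd33 0.25, Stab1 0.16 and Zfp39 0.21.

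On simulated data with 5 against 5 libraries, 31.3% of 1.5-fold changes were recovered.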

Other observations

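The gene families in this part were chosen, and their Fisher's exact tests run, only after the result was seen.

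Some lysosomal proteases and subunits of the pump that acidifies lysosomes fell in the MIA libraries, in which the homeostatic and complement lists were lower (mean log2 fold change −0.47 each) and the endothelial list higher (1.36). Of 13 measured cathepsin genes 6 fell and 1 rose, a share of 46.2% lower against 4.54% among all other genes (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.000117). Ctsd, a major lysosomal aspartic protease, fell by 0.54 ± 0.13 on the log2 scale (SE), Ctss, which microglia use to trim antigens, by 0.64 ± 0.11 and Ctsz by 0.54 ± 0.12, while Ctsw of lymphoid cells rose from 4.67 to 14.8 CPM. Of 20 vacuolar ATPase genes 5 fell, among them the accessory subunit genes Atp6ap1, by 0.34 ± 0.07, and Atp6ap2, by 0.44 ± 0.10 (adjusted p = 0.00865 by the same exact test). Ctsd and Atp6ap2 did not pass edgeR without MIA 5 (adjusted p of 0.0542 and 0.0588).

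Solute carriers changed in both directions, and some collagens rose. Of 272 solute carrier genes 28 rose, a share of 10.3% against 5.67% among all other genes (Fisher's exact test, adjusted p = 0.00978), and 20 fell, a share of 7.35% against 4.53% (exact adjusted p = 0.0769). The lactate carrier Slc16a1 went from 372 to 930 CPM and the glutamine carrier Slc38a5 from 144 to 432 CPM, and the arginine carrier Slc7a1 and the thyroid hormone carrier Slco1c1 rose by 1.45 and 1.18 on the log2 scale. Brain endothelium is known to express these 4 transporters, and the endothelial list rose in the same libraries. Of 36 collagen genes 7 rose and none fell (exact adjusted p = 0.00978), with Col4a1, of the vessel basement membrane, at 221 CPM in CON and 392 in MIA, and Col4a2 rising by 0.81; Col4a2 did not pass edgeR without MIA 5 (adjusted p = 0.0526). Of 9 claudin genes only Cldn5 rose (exact adjusted p = 0.590).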
